A study of Homo sapiens with 6 samples.

How the data were processed

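RNA from N/TERT-1 cells, a human keratinocyte line immortalised with telomerase, was profiled on 6 Illumina BeadChip arrays after biotin labelling of the amplified RNA. Per the labels' protocols, the cells received 30 nM of either a non-targeting siRNA or a pool of siRNAs against FSTL1, and total RNA was taken on day 2. Groups and replicate numbers were read from the sample titles, with 3 arrays per group. The labels do not say that the arrays of a group came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

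Each deposited signal intensity is a linear, background-subtracted bead signal for 1 probe on 1 array, with negative values in every column and no scaling between arrays, as read from the values and the file headers. Beside each signal the authors deposited a detection p-value, per the file headers, which compares the probe with that array's negative control beads. GenomeStudio 1.9.0 is named in the submitters' processing notes. A table of the authors' normalized intensity was also deposited. Its columns share the same quartiles and maximum and hold negative values, so they were read as quantile-normalized signal on a linear scale. The rank correlation of each of its columns with the signal of the same array was 1, and the highest with another array was 0.922. Any centring of that table is not given in the sources used here, and no genome build is named, so no coordinates are given.

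The table held 47322 probes. The platform annotation gave 30113 of them 1 gene symbol, 8 several symbols and 17201 none. Of the named probes, 30074 matched a current gene by Entrez identifier and 39 did not and kept their annotated name. Probes with several symbols or none stayed out of the gene tests.

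The deposited signals were processed with limma 3.58.1 in R 4.3.3. Function neqc was used, with the negative controls' mean and spread inferred from the detection p-values, an offset of 16, quantile normalization between arrays and a log2 transform. Probes were kept where the detection p was under 0.05 on at least 3 of the 6 arrays, which left 19531 probes, 14882 of them named. Where a gene had more than 1 kept probe, as 2989 genes did, the probe with the highest mean log2 value over all 6 arrays stood for it. This gave 11193 genes. A linear model with group as its only term was fitted with lmFit and moderated with eBayes, two-sided, with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. Fold changes are FSTL1 siRNA over control siRNA and intervals are 95% intervals of the model. A probe not detected on any array of a group has only a bound there. Its fold is given as "at least", against the mean of, per array, the higher of the lowest detected signal and the probe's own.

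A total of 25 gene lists was fixed before the data were examined, and the 20 with at least 5 measured genes were tested with camera at a preset correlation of 0.01, adjusted over the 20 lists. Camera with an estimated correlation and fry were run beside it. For each list, the number of members past the threshold is given over all genes and adjusted over the list alone. The mean of each list per array was also compared with a two-sided exact permutation test, which cannot give a p below 0.1 with 3 arrays against 3.

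Genes were named by a rule fixed before the data were examined. FSTL1, DIAPH1 and PLAU were among those always named, with up to 12 genes of the largest increase and 12 of the largest decrease among genes that passed and whose groups did not overlap. From each list came up to 4 members that passed or, where none did, the 2 with the smallest p. An item the rule also covers is not reported here, and other genes are named as having been chosen after their values were seen.

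The steps were tested on simulated data with the 11193 genes and the spread of these arrays. Over 20 simulations, 56.7% of genes changed by 0.5 on the log2 scale and 92.8% of those changed by 1 were recovered, and 5.68% of the calls were false. The spread of each simulated gene was drawn from the fitted prior of the moderated test, whatever its brightness, with normal noise. A false share near the threshold was thus largely built in, and these rates need not hold for the real arrays. A simulated shift of 0.2 in the keratinocyte migration list was recovered in 20 of 20 simulations, and 2 of 380 tests of other lists passed. The simulated genes varied independently, and each list member got the same shift. In these data the list's mean change was 0.06, with an estimated correlation between members of 0.05. The simulation therefore does not give the power for a shift as small or as uneven as that.

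Alternatives covered the background correction and its offset, the scaling between arrays, the authors' normalized values, the filter on dim probes, the choice of probe, the replicate number as a block, the prior of the moderated test, array weights, each array left out in turn, the threshold, a minimum fold of 1.5 and the set test. Figures were drawn with matplotlib 3.10.9.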

Results

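The transcriptome of N/TERT-1 keratinocytes was compared 2 days after transfection with 30 nM of a non-targeting siRNA or of an siRNA pool against FSTL1, with 3 arrays in each group. FSTL1 encodes follistatin-like 1, a secreted glycoprotein, and the series concerns its part in keratinocyte migration. Between 18805 and 20017 of the 47322 probes were detected on each array, or 39.7% to 42.3%, and mean signals ran from 461 to 527. Correlations of log2 signal over the 11193 tested genes were 0.995 to 0.996 within groups and 0.993 to 0.995 between groups. The first principal component, with 32.0% of the variance, separated the groups, and control replicate 1 lay farthest out on it at -13.4. In the deposited signals before normalization, no probe had exactly the same value on any pair of arrays. The number of arrays limits the precision of every value below.

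The first comparison asked whether the siRNA pool lowered its target. FSTL1 mRNA fell to 31.5% of the control level (95% interval 28.9% to 34.3%) at its 1 named probe, ILMN_2201678. Its normalized log2 signal was 10.81 ± 0.02 (SD, n = 3) after control siRNA and 9.14 ± 0.03 (SD, n = 3) after FSTL1 siRNA, a change of -1.67 with a standard error of 0.05 (limma, adjusted p = 0.000118). The deposited signal before normalization was 1721 ± 122 in the controls and 567 ± 13.5 in the FSTL1 siRNA arrays, and all 3 treated arrays lay below all 3 controls. No other gene had a change as large.

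The second comparison asked which other transcripts differed after FSTL1 siRNA. Beside FSTL1, the 4 genes with the smallest p among those that fell were the interferon-induced OASL, CXCL10, GBP1 and IFIT2, while the largest fall was that of PPP3R1. CXCL10, a chemokine gene induced by interferon, fell by 0.89 on the log2 scale, from 11.88 ± 0.07 to 10.99 ± 0.03 (SD, n = 3 each; limma, adjusted p = 0.00732). IFIT2 and OASL, which encode antiviral effectors, fell by 0.85 (adjusted p = 0.0150) and 0.80 (adjusted p = 0.00732). IFNB1, the gene of interferon beta itself, fell by 0.80, from 7.15 ± 0.10 to 6.35 ± 0.09 (SD, n = 3 each; limma, adjusted p = 0.0191). GBP1, an interferon-induced GTPase gene, fell by 0.77 (limma, adjusted p = 0.00981).

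**Figure D1:**
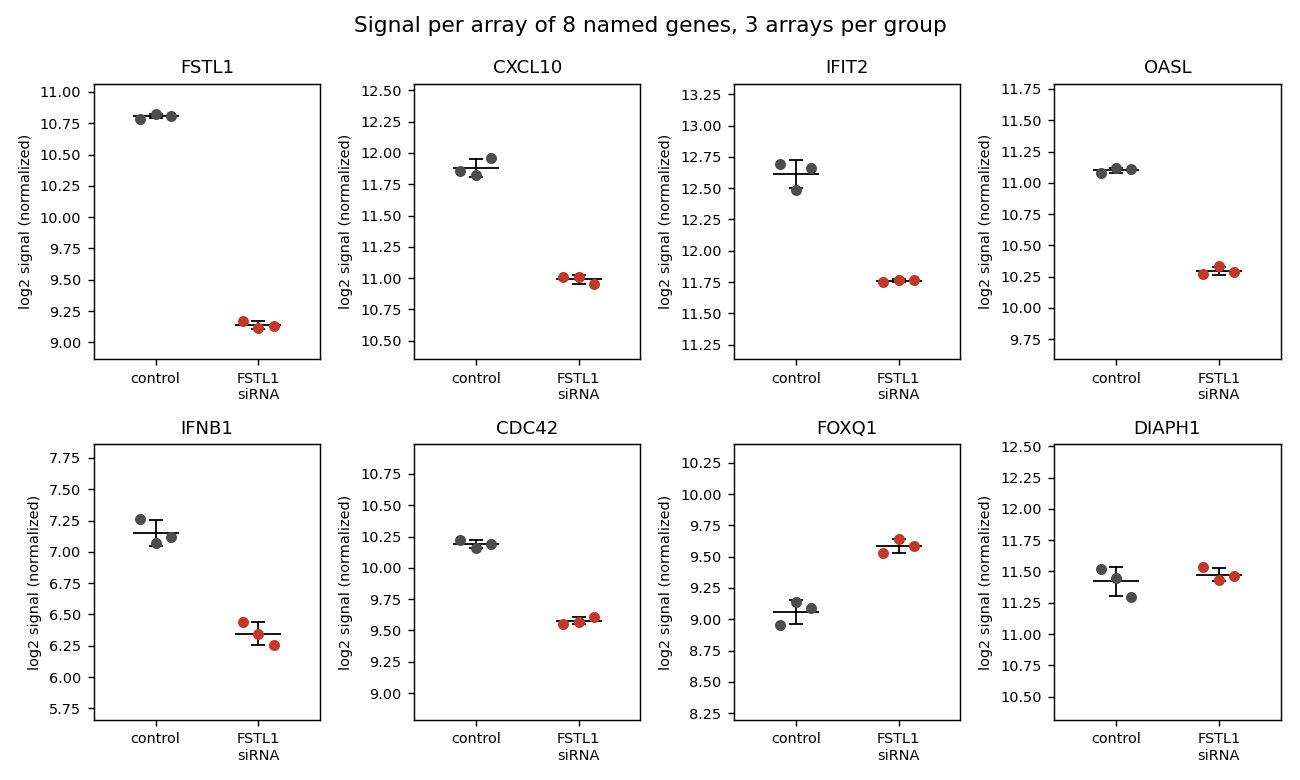
Normalized log2 signal of 8 named genes on each array, with control siRNA arrays in grey and FSTL1 siRNA arrays in red, and bars for the mean and SD of 3 arrays. FSTL1, CXCL10, IFIT2, OASL, IFNB1 and CDC42 lie lower and FOXQ1 higher on all FSTL1 siRNA arrays, while the groups overlap for DIAPH1.

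In all, 39 of 11193 genes changed, 3 higher and 36 lower (limma, adjusted p under 0.05), and in each of them the groups did not overlap. Over all genes the groups did not overlap for 21.7%, against 10% by chance. At an unadjusted p under 0.05 there were 852 genes higher and 819 lower, where chance gives about 560 in all. RSAD2, which encodes the antiviral enzyme viperin, fell by 0.78 and BATF2, an interferon-induced transcription factor gene, also fell by 0.78. PPP3R1, the regulatory subunit of calcineurin, fell by 0.95 from 8.61 ± 0.04 to 7.66 ± 0.21 (SD, n = 3 each; limma, adjusted p = 0.0281). FERMT2, which encodes the integrin-binding adhesion protein kindlin-2, fell by 0.81, and IL1RN, the interleukin-1 receptor antagonist, by 0.74. The histone gene H2AC18, one of a family of near-identical genes, fell by 0.71, but its second kept probe gave -0.22, so its value is uncertain.

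The 3 genes that rose were METTL16, ARHGAP45 and FOXQ1. METTL16, an RNA methyltransferase gene, was not detected on any control array and was detected on all 3 FSTL1 siRNA arrays, at least 1.42-fold higher (limma, adjusted p = 0.0176). ARHGAP45 rose by 0.61 on the log2 scale and FOXQ1, a forkhead transcription factor gene, by 0.52, from 9.06 ± 0.10 to 9.58 ± 0.06 (SD, n = 3 each; limma, adjusted p = 0.0490). ARHGAP45 was dim, at 5.57 in the controls, against lowest detected signals of 5.24 to 5.35 on the 6 arrays. Among the 39 genes, 9 had further kept probes, and 8 of these 10 probes moved in the same direction, 4 of them at an unadjusted p under 0.05. The calls other than FSTL1 depended on having all 6 arrays: without control replicates 1, 2 and 3 in turn, 1, 3 and 1 genes passed as lower, without FSTL1 siRNA replicates 1, 2 and 3, 1, 5 and 1, and none passed as higher. Of the 39, 33 passed in none of these fits. All 39 kept their direction, and an unadjusted p under 0.05, in every such fit that tested them. This was largely fixed in advance, since the 39 were chosen on the same arrays and their groups did not overlap. With an intensity trend and robust prior in the moderated test, 181 genes passed as higher and 252 as lower, including 37 of the 39.

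Interferon-stimulated genes as a group were lower after FSTL1 siRNA. Of 37 measured members, 8 fell when adjusted over all genes and 31 when adjusted over the list alone, none rose either way, and 35 lay below 0. The mean change was -0.33 (camera, adjusted p = 1.47e-27), with adjusted p = 0.00400 with an estimated correlation. Beside IFIT2, OASL and RSAD2, CMPK2, a mitochondrial nucleotide kinase gene induced with RSAD2, fell by 0.65 (limma, adjusted p = 0.0212). The mean of the list was 11.98 ± 0.01 in the controls and 11.65 ± 0.01 after FSTL1 siRNA (SD, n = 3 each), with an exact permutation p of 0.1, the smallest that 3 arrays against 3 allow. With median scaling in place of quantile normalization, 2 members fell over all genes and 16 when adjusted over the list alone. The 8 members that fell over all genes were 0 or 1 with any 1 array left out, and 0 with the replicate number as a block. They were 2 with the authors' values or all kept probes tested, and 3 with no background correction or no filter on dim probes. They were 14 with an offset of 50, 15 with detection p under 0.01 on all arrays and 29 with an intensity trend and robust prior.

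Inflammatory and NF-kappaB target genes were also lower on average, by -0.15 over 25 measured members (camera, adjusted p = 0.00131). This call was lost with an estimated correlation, at adjusted p = 0.0645 with an estimated correlation. CXCL10, IL1RN, CCL5 and PI3 fell over all genes, and 6 members fell when adjusted over the list alone. CCL5, a chemokine gene, fell by 0.58 (limma, adjusted p = 0.0212), though its second probe gave -0.16, and PI3, the protease inhibitor elafin, by 0.45 (limma, adjusted p = 0.0402). CXCL10, CCL5 and IL1RN are also known to respond to interferon. Other members such as CXCL8, at 0.27, and IL1B, at 0.07, chosen after their values were seen, did not pass (limma, adjusted p = 0.239 and 0.641). Without any 1 array, 0 or 1 of the 4 passed over all genes. On all 6 arrays, 2 members passed with no background correction, median scaling, the authors' values or no filter on dim probes. With all kept probes tested 1 passed, and with the replicate number as a block 0 did. The count was 5 with detection p under 0.01 on all arrays and 6 with an intensity trend and robust prior.

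Genes of epidermal differentiation and the cornified envelope had a mean change of -0.14 over 29 measured of 59 fixed members (camera, adjusted p = 0.000590), a call lost at adjusted p = 0.0605 with an estimated correlation. Among those not measured were KRT1, IVL, LORICRIN and FLG, whose probes did not pass the detection filter. No member passed over all genes in limma, 5 fell when adjusted over the list alone, and at an unadjusted p under 0.05 there were 11 lower and 1 higher. TGM1, the transglutaminase that cross-links the cornified envelope, changed by -0.53 with a standard error of 0.09 when adjusted over the list alone (limma, adjusted p = 0.0819 over all genes). A2ML1, a protease inhibitor gene of the upper epidermis, followed at -0.46 (limma, adjusted p = 0.119 over all genes). The 5 members were 7 without FSTL1 siRNA replicate 1, 3 without FSTL1 siRNA replicate 3, 1 without control replicate 1 and 0 without control replicate 2, control replicate 3 or FSTL1 siRNA replicate 2. They were 10 with detection p under 0.01 on all arrays, 9 with an intensity trend and robust prior and 3 with the mean over a gene's probes. They were 1 with no background correction, the authors' values, no filter on dim probes, all kept probes tested or the replicate number as a block, and 0 with median scaling. Of the basal keratinocyte and hemidesmosome list, none of 14 measured members passed in limma, with 2 higher and 0 lower at an unadjusted p under 0.05. PLEC, the hemidesmosomal plakin gene, was at 0.22 and LRIG1 at 0.19 (camera for the list, adjusted p = 0.678).

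Cell cycle and mitosis genes were higher together after FSTL1 siRNA. All 32 measured members lay above 0, with a mean change of 0.23 (camera, adjusted p = 2.66e-17; adjusted p = 0.0145 with an estimated correlation). No single member passed over all genes in limma, 22 rose when adjusted over the list alone, and 25 were higher and 0 lower at an unadjusted p under 0.05. With an intensity trend and robust prior, 19 passed over all genes. KIF20A, a mitotic kinesin gene, was at 0.33 ± 0.06 (SE) and RRM2, the small subunit of ribonucleotide reductase, at 0.31 ± 0.06 (SE), both rising when adjusted over the list alone. The list's mean was 10.33 ± 0.02 in the controls and 10.55 ± 0.02 after FSTL1 siRNA (SD, n = 3 each; exact permutation p = 0.1). The 22 members were 12 without control replicate 3 and also 12 without FSTL1 siRNA replicate 3.

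DNA replication genes were higher as well, by 0.11 over 29 measured members (camera, adjusted p = 1.39e-05; adjusted p = 0.0387 with an estimated correlation). No member passed over all genes or when adjusted over the list alone in limma, while 11 were higher and 0 lower at an unadjusted p under 0.05, and 3 passed as higher with an intensity trend and robust prior. MCM6 and MCM7, subunits of the replicative helicase, were at 0.22 and 0.21 (limma, adjusted p = 0.165 and 0.193). All 3 FSTL1 siRNA arrays lay above all 3 controls in the mean of the list.

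**Figure D2:**
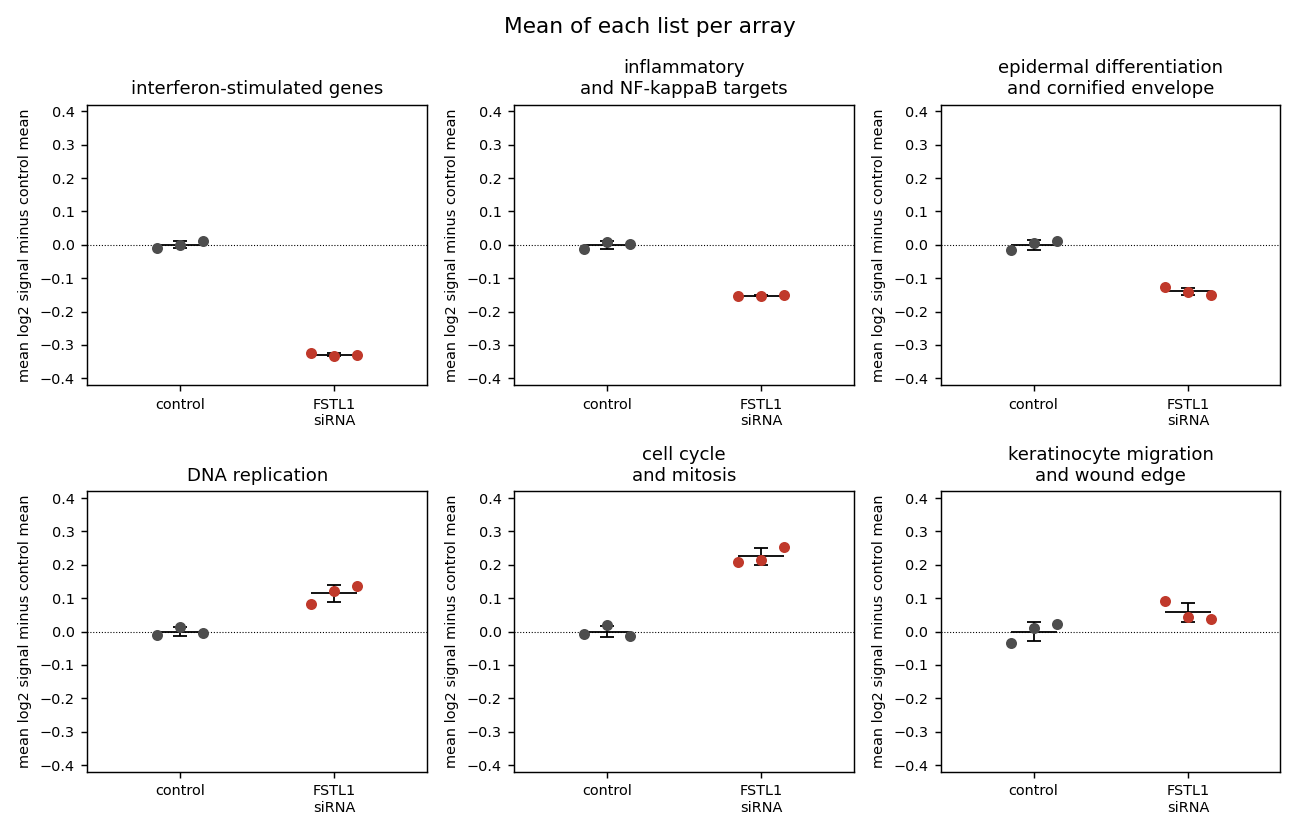
Mean log2 signal of 6 gene lists on each array, minus the control mean, with control siRNA arrays in grey, FSTL1 siRNA arrays in red, and bars for the mean and SD of 3 arrays. The interferon, inflammatory and differentiation lists lie below 0 and the replication and cell cycle lists above 0 on all 3 FSTL1 siRNA arrays, and the migration list, which did not pass camera, also lies above the controls on all 3, by 0.06 on average.

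The study's title concerns migration, and the keratinocyte migration and wound edge list was the test fixed for it. Of its 34 fixed members, 25 were measured. They had a mean change of 0.06 and a median of 0.06, which did not pass (camera, adjusted p = 0.0821; adjusted p = 0.407 with an estimated correlation; fry, adjusted p = 0.0568). The mean of the list was 10.66 ± 0.03 in the controls and 10.72 ± 0.03 after FSTL1 siRNA (SD, n = 3 each), with all 3 treated arrays above all 3 controls (exact permutation p = 0.1, the smallest possible). No member passed over all genes in limma, and 6 were higher and 1 lower at an unadjusted p under 0.05. VIM, the intermediate filament gene vimentin, rose when adjusted over the list alone, by 0.33 with a standard error of 0.05 (limma, adjusted p = 0.0647 over all genes). MMP14, a membrane-bound matrix metalloprotease gene, was at 0.36 (limma, adjusted p = 0.159). PLAU, the urokinase plasminogen activator gene, was at 0.14, with an interval from 0.00 to 0.28 (limma, adjusted p = 0.322). DIAPH1, a formin that nucleates actin filaments, was at 0.05, with an interval from -0.12 to 0.23 (limma, adjusted p = 0.790), and its direction was reversed in the mean over its probes. These 2 genes and FSTL1 were the 3 measured members of a further list, too small to test, and had a mean of -0.49 and a median of 0.05. FSTL1, the siRNA target, was at -1.67, so that mean was set by the knockdown and says nothing about the other 2 genes.

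In the actin and focal adhesion list, CDC42, a small GTPase gene, fell by 0.62, from 10.19 ± 0.03 to 9.58 ± 0.03 (SD, n = 3 each; limma, adjusted p = 0.0176). Its other kept probes gave -0.24 and 0.14, so the value rests on 1 probe. It was the only 1 of 31 measured members to pass over all genes, and 1 rose and 2 fell when adjusted over the list alone. The list as a whole had a mean of 0.00 and did not pass (camera, adjusted p = 0.793).

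**Figure D3:**
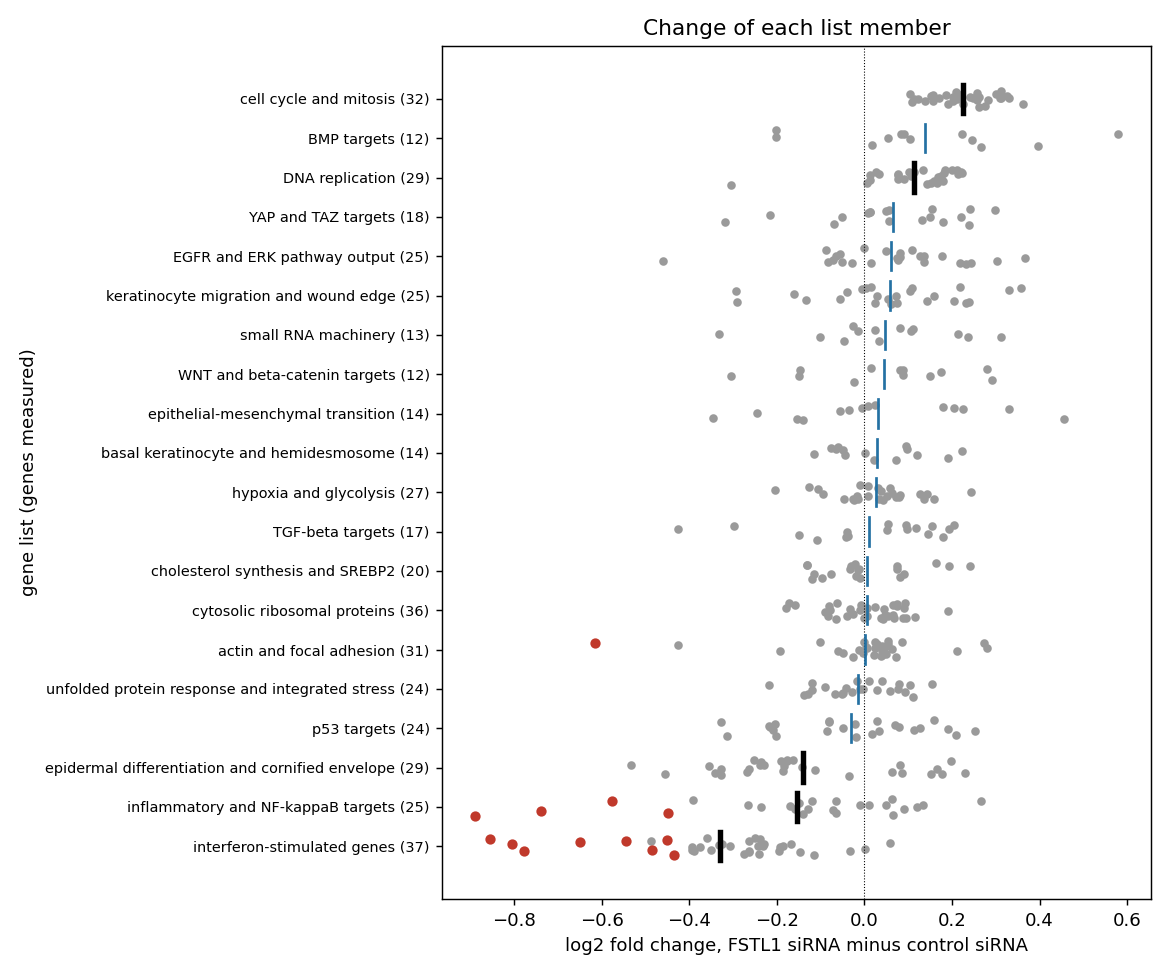
Log2 fold change of each measured member of the 20 tested lists, FSTL1 siRNA minus control siRNA, with the number of genes measured beside each name. Red points passed the threshold over all genes, and thick black bars mark the means of the 5 lists that passed camera with the preset correlation, blue bars those of the other lists.

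The remaining lists did not pass camera with the preset correlation. EGFR and ERK pathway output had a mean of 0.06 (adjusted p = 0.0821) and passed in 2 of 20 alternatives. These were fry, which tests whether members move on balance in 1 direction (adjusted p = 0.0148), and camera after median scaling, with a mean of 0.13 (adjusted p = 0.0416), and over all alternatives the adjusted p ran from 0.0148 to 0.247. When adjusted over the list alone, 3 of its 25 members rose and 1 fell, and 0 passed over all genes in limma, with 6 higher and 1 lower at an unadjusted p under 0.05. EMP1, a membrane protein gene, was at 0.37 and JUNB, an AP-1 subunit gene, at -0.46 (limma, adjusted p = 0.101 and 0.0836 over all genes). The epithelial-mesenchymal transition list, with a mean of 0.03 (camera, adjusted p = 0.793), also passed fry (adjusted p = 0.00750), with 2 members higher and 1 lower when adjusted over the list alone, VIM and TWIST2 being the 2 higher. That list mixes mesenchymal genes such as VIM with epithelial genes such as CDH1, which such a transition would move in opposite directions. A test for 1 direction therefore cannot decide whether a transition took place. TWIST2, a basic helix-loop-helix factor gene, was at 0.46 (limma, adjusted p = 0.0910).

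Targets of BMP, TGF-beta, WNT and YAP signalling did not pass camera with the preset correlation on all 6 arrays either. BMP targets had a mean of 0.14 over 12 of 23 fixed members (camera, adjusted p = 0.160), but of -0.0014 with no filter on dim probes, with means from -0.0014 to 0.20 over the alternatives. Among the 12 were ID1, a direct BMP target, at -0.20 and FST, which encodes follistatin, at 0.22. TGF-beta targets had a mean of 0.01 over 17 members (camera, adjusted p = 0.793). Among them TAGLN, an actin-binding protein gene, fell when adjusted over the list alone, at -0.43 (limma, adjusted p = 0.0970 over all genes), and LTBP2 was at 0.19. WNT and beta-catenin targets, with DKK1 at 0.28 and ZNRF3 at -0.30, had an adjusted p = 0.504, and YAP and TAZ targets, with PTPN14 at 0.24 and CRIM1 at -0.32, an adjusted p = 0.127. The YAP and TAZ list passed without FSTL1 siRNA replicate 3, at a mean of 0.09 (adjusted p = 0.0493, the lowest of a range up to 0.443 over its alternatives). In these 4 lists 0 members passed over all genes in limma, while 2, 2, 2 and 5 were higher and 1, 2, 1 and 1 lower at an unadjusted p under 0.05, in the order BMP, TGF-beta, WNT and YAP.

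Stress and metabolic lists stayed near 0. The p53 target list had a mean of -0.03 (camera, adjusted p = 0.678), with BAX, a pro-apoptotic gene, lower when adjusted over the list alone at -0.33 and TNFRSF10B at 0.19. The unfolded protein response list was at -0.01 (adjusted p = 0.678), with ATF3 at -0.22 and PDIA4 at 0.15, and hypoxia and glycolysis at 0.03 (adjusted p = 0.678), with ADM at -0.20 and HK2 at 0.16. Cholesterol synthesis genes had a mean of 0.01 but a median of -0.02 and a test directed downward (adjusted p = 0.941), with ACAT2 at 0.19 and EBP at 0.16. The small RNA machinery list, which holds the Argonaute genes, was at 0.05 (adjusted p = 0.489), and 1 member rose and 1 fell when adjusted over the list alone, TNRC6A at 0.31 and AGO3 at -0.33. Cytosolic ribosomal protein genes were at 0.01 (adjusted p = 0.789), with RPL35 at 0.19 and RPL29 at -0.18. None of the members of these 6 lists passed over all genes in limma. At an unadjusted p under 0.05, in the order given, 2, 1, 2, 2, 2 and 1 members were higher and 4, 1, 1, 0, 1 and 0 lower.

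Markers of other cell types were too few among the measured genes to test as lists, with 2 for fibroblasts, 1 for melanocytes, 4 for endothelial cells and leukocytes and 2 for simple epithelium. FAP, a fibroblast protease gene, was at -0.47 and fell when adjusted over its list alone (limma, adjusted p = 0.110 over all genes), and COL1A2 was at -0.25. MITF was at -0.01, LYZ at -0.42, CD79A at 0.10, KRT8 at 0.04 and MUC1 at -0.04, none of which passed (limma, adjusted p from 0.522 to 0.992).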

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

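FSTL1 stayed past the threshold in all alternatives, with changes from -1.59 to -1.71. The cell cycle, DNA replication and interferon lists kept their direction and passed in 20 of 20 alternatives, the differentiation and inflammatory lists in 19 of 20, both lost only with an estimated correlation, where 3 lists passed in place of 5. There were 6 with median scaling (EGFR and ERK output added), 6 without FSTL1 siRNA replicate 3 (YAP and TAZ targets added) and 7 with fry (EGFR and ERK output and the epithelial-mesenchymal list added). The migration list passed in none, with means from 0.03 to 0.12 and adjusted p from 0.0568 to 0.457. The numbers of single genes moved far more, and the cause was not tested unless stated. With no background correction 0 genes were higher and 14 lower, with an offset of 50 25 and 95, with median scaling 1 and 7, with the authors' normalized values 0 and 12, with no filter on dim probes 1 and 14, with detection p under 0.01 on all arrays 29 and 103, and with all kept probes tested 0 and 5, all 5 among the 39. The trend and robust prior gave 181 and 252, array weights 5 and 45, an unadjusted p 852 and 819, an adjusted p under 0.01 0 and 4, and a 1.5-fold minimum on fitted folds 2 and 21, where METTL16, 1 of the 2, has a bound of only 1.42-fold. Without any 1 array the counts ran from 0 to 0 higher and from 1 to 5 lower. Fewer arrays leave fewer degrees of freedom in those fits. Every result outside these counts was also compared with the main setting in each alternative, leave-one-out fits aside. Of these pairs of a result and an alternative, 34 passed only in the alternative and 74 no longer passed, while 888 stayed the same. The 888 include results that passed in neither setting, so they do not measure how stable the calls were. With leave-one-out fits included, FOXQ1 still passed in 5 of 18 alternatives, RSAD2 in 6 of 18 and CXCL10 in 13 of 18. The replicate numbers did not pair the samples: residual correlations of same-numbered arrays were -0.01, -0.01 and -0.08, and with the number as a block 0 genes were higher and 1 lower, FSTL1. Slide as a block was not run, since the columns give no slide. Signal over background limits dim genes, as with METTL16, not detected in controls. Scaling moved the median of all genes by at most 0.09.

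Some results that did not pass changed sign in some alternatives, all of them near 0 in the main setting except BMP targets at 0.14, and the cause was not tested. MITF was 0.077 with no background correction, 0.014 with median scaling, 0.076 with the authors' values and 0.031 with array weights. Median scaling put p53 targets at 0.032 and the unfolded protein response at 0.054. Cyclic loess put the actin list at -0.0018 and ribosomal proteins at -0.0058. No filter put TGF-beta targets at -0.00043, BMP targets at -0.0014 and the unfolded protein response at 0.0030. Strict detection put the epithelial-mesenchymal list at -0.00037 and cholesterol synthesis at -0.0054. Ribosomal proteins were -0.0026 with all probes and -0.0044 with the mean over probes, where DIAPH1 was -0.055, and the actin list was -9.3e-05 with array weights. With 1 array left out, ranges were -0.0068 to 0.0098 for the actin list, -0.014 to 0.034 for TGF-beta targets, -0.0065 to 0.029 for cholesterol synthesis, -0.011 to 0.014 for ribosomal proteins, -0.14 to 0.055 for MITF, -0.22 to 0.093 for MUC1, -0.020 to 0.071 for KRT8 and -0.0097 to 0.10 for DIAPH1.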

Other observations

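The tests of scaling, brightness, IFNB1 and probe saturation below were chosen after the results were seen. Several genes outside the fixed lists also fell, and they are named here after their values were seen. CFB and C1S, complement genes that keratinocytes express, changed by -0.63 and -0.50 (limma, adjusted p = 0.0490 for both). CEACAM1, an adhesion molecule gene, changed by -0.51, with its second probe at -0.53, and JAK1, a kinase that carries interferon receptor signals, by -0.43 (limma, adjusted p = 0.0402 for both). SPRR2G and SERPINB13, genes of the keratinising epidermis, changed by -0.61 and -0.56 (limma, adjusted p = 0.0191 and 0.0429). SPRR2G was dim, at 5.90 in the controls and 5.30 after FSTL1 siRNA, where 2 of 3 arrays detected it. The lowest detected signals of the 6 arrays were 5.24 to 5.35, so the size of its fall is uncertain.

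The 6 arrays make 10 splits into 3 and 3, too few for a share under 0.05. The real split gave 36 genes on the side with more calls, 3 on the other and 5 lists. The highest of the other splits gave 0, 0 and 3, so 1 of the 10 splits reached each of these results, the real one. Every other split still shifted 1 to 3 lists. Each of them puts arrays of both groups on both sides, so any group difference widens the spread within a side. Few gene calls were therefore likely in them, and the splits cannot decide whether the results arose by chance.

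Interferon-stimulated genes were lower after FSTL1 siRNA. Without scaling between arrays, their mean minus the median of all genes was -0.33. Its standard error was 0.03 across the 37 genes rather than between arrays. The value argues against scaling as the whole cause. The mean of -0.33 lay outside the middle 95% of 10000 random lists matched on brightness, -0.03 to 0.04, which argues against a brightness-dependent bias. A candidate explanation that stays open is a different innate response to the transfected siRNAs themselves, since IFNB1, which RNA sensing induces, changed by -0.80 (95% interval -0.99 to -0.62). With 1 control siRNA and no untransfected cells, this cannot be told apart from an effect of lower FSTL1.

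Cell cycle and DNA replication genes, 61 in all, were higher after FSTL1 siRNA. Without scaling, their mean minus the median of all genes was 0.18, with a standard error of 0.01 across the 61 genes rather than between arrays. With scaling, their mean was 0.17 against -0.03 to 0.03 for the middle 95% of the brightness-matched lists. Both values argue against scaling and brightness as the whole cause. No biological explanation was tested, nor an effect of the siRNA pool other than on FSTL1.

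The fall of the interferon-stimulated genes was uneven, with MX1 at 0.00, IFI27 at -0.03 and IFITM3 at 0.06 (none past the threshold in limma), picked after their values were seen. Saturation of bright probes could hide a change. Apart from MX1, 3 list members were brighter than IFITM3, namely IFIT1, ISG15 and IFI6, at -0.45, -0.26 and -0.19. Their mean change was -0.30, with a standard error of 0.08 across these 3 genes rather than between arrays. Their falls argue against saturation for IFI27 and IFITM3, though the fall was smallest for IFI6, the brightest of the 3 at 14.99 in the controls. For MX1, at 15.09 in the controls, only 7 tested genes were as bright and none of them was in the list, so saturation and a true lack of change cannot be told apart.

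PPP3R1, FERMT2, CDC42 and DCAKD, which belong to no interferon list here, changed by -0.95, -0.81, -0.62 and -0.67. The siRNA sequences are not given in the sources used here, so matches between them and these transcripts were not searched.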
